A study of Homo sapiens with 61 samples.

How the data were processed

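DNA from whole blood of 10 people with hepatocellular carcinoma (HCC) and 51 healthy controls was extracted with a Qiagen blood and tissue kit. It was made into dual-indexed libraries by enzymatic cytosine conversion (NEBNext Enzymatic Methyl-seq), per the labels' protocols. The series' design text calls the assay whole-genome bisulfite sequencing, and the protocols name the enzymatic kit, which needs no bisulfite. Sequencing was paired-end on an Illumina instrument, per the series' design text. FastQC, Trim Galore, cutadapt, BSMAP, SAMtools, Picard and bedtools and the build hg38 are named per the submitters' processing notes; their versions, settings and order are not given in the sources used here. BSMAP aligns reads in which unmethylated cytosines read as T, as enzymatic conversion also produces, so it suits this assay.

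The authors deposited 1 table per group, with 1 row per CpG. Per the file headers it holds the count of reads and of methylated reads, over both strands and per strand, and their ratio, which is the methylation level as a fraction. The deposited fraction equals methylated over all reads in every row within rounding, and levels here were computed from the deposited counts and are given in percent. Each table is a pool over the group, and whether every library of the group went into it over its whole length is not given in the sources used here. No values per person were available, so no test between people, no leaving out of single people and no regrouping of samples was run. No row in either table has under 3 reads, so CpGs with fewer are not listed. How the authors treated duplicates, overlapping read pairs and read ends, which can shift levels, is not given in the sources used here either.

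CpGs listed in both tables with at least 10 reads in each were kept (27409352 of 27729971 autosomal CpGs). Chromosomes X and Y were left out, because their levels follow the sex of donors. The mitochondrial genome served only as a check of conversion, and unplaced contigs were not used. Tiles were fixed 1000 bp windows with at least 5 CpGs, and a tile, region or promoter level is the mean over its CpGs. Regions of intermediate methylation were runs of at least 5 consecutive CpGs, neighbours at most 200 bp apart, each with a mean of the 2 pools' levels from 35 to 65%. Choosing on the mean of both pools gives the shallower HCC reads more pull on which CpGs enter, so regions chosen on the control pool alone are given too. The size rule was a difference of at least 10 percentage points. Imprinted loci were the region with most CpGs within 10 kb of each listed gene, counted once where genes share it. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the same coordinates as hg38. It gives no strand, so the planned promoter windows at transcription starts could not be placed. The gene end with more measured CpGs was used, from 1500 bp outside to 500 bp inside the gene, with at least 5 CpGs, and for some genes this is the far end. This definition replaced the planned one and was set with the deposited data at hand. No genome sequence was used, so isolated CpGs were not split by their flanking bases. Of 268 listed names 265 matched the table, by symbol or a synonym of only 1 gene, among them 2 names of 1 gene in the age-associated list, which was counted once. Of the matched genes 2 lie on chromosome X and were left out.

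Fisher's exact test (2-sided) with Benjamini-Hochberg adjustment at 0.05 compared the 2 pools of reads in 2 ways. The first took the region's mean level times all reads summed over its CpGs. It treats CpGs on one read as independent, so its p-values are too small. The second took the region as 1 site at its mean depth, which is conservative for long regions. Intervals of differences at regions, loci and promoters are Newcombe's at 95%, from Wilson bounds at the mean depth. The interval of the genome-wide difference is a normal one that sums the binomial variance of every CpG, as if all reads at all CpGs were independent. PCR copies are not independent molecules, so intervals cover counting error only. Differences on plus- and minus-strand reads, which come from different molecules, were set side by side. A single CpG at the median depth of the HCC pool has 33 reads. Random lists for imprinted loci were drawn 10000 times, each member from the 50 other regions nearest in number of CpGs. For promoters they were matched in 10 classes of level and 5 of number of CpGs. Percentiles describe these 2 pools.

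The test was tested on simulated data for 30652 tiles of chromosome 21 in the comparison of HCC with control. With independent reads, the first form called 0.049% of unchanged tiles and recovered 96% of tiles changed by 20 points and 56% of those changed by 10 points. With whole reads shared by all CpGs of a tile it called 48.7% of unchanged tiles, while the second form called 0.003%. The second form recovered 13% (independent reads) and 16% (whole reads) of changes of 20 points and 0% of those of 10 points. The simulation came after differences, size counts and test counts on the deposited data had been looked at. An earlier form of the first test, on summed methylated reads, called 1.97% of unchanged tiles in it with independent reads. That form was replaced although its counts of tiles and regions had already been seen. Of tiles that differed by at least 10 points it passed 13360 lower and 3687 higher, and of regions 3154 and 354, fewer than the form used here. Of tiles of any size it passed more, 272003 against 187097, and of regions of any size fewer, 4335 against 4346.

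Named genes followed a rule fixed before the data were examined. It took 10 imprinted genes (H19, KCNQ1OT1, SNRPN, MEST, PEG3, GNAS, GRB10, PLAGL1, MEG3 and PEG10) and up to 15 other imprinted genes that differed by at least 10 points. It also took the 10 regions of intermediate methylation with the largest difference in each direction by nearest gene, the 10 protein-coding promoters with at least 10 CpGs in each direction, and the 2 genes in each direction of each list. Some genes that this rule takes are not reported here. The 14 lists, also fixed before, were imprinted genes, neutrophil, monocyte, T cell, B cell, NK cell, eosinophil and basophil, erythroid and hepatocyte markers, tumour-methylated promoters in hepatocellular carcinoma, age-, smoking- and inflammation-associated sites, and the DNA methylation machinery. Alternatives tried were other coverage minimums, CpG minimums, tile sizes, level ranges, thresholds, distances, promoter windows, selections and centring. Alternatives chosen after seeing the data left out CpGs over 3 times the median depth, required both strands, removed the drop expected from depth, or kept the last 11 autosomes in the order of the tables. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.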

Results

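Whole blood DNA methylation was measured across the genome in 10 people with hepatocellular carcinoma (HCC), a primary cancer of the liver, and in 51 healthy controls. Libraries were made by enzymatic methyl sequencing, in which enzymes protect methylated cytosines and convert unmethylated ones, so that methylated cytosines are read as C and the rest as T. The deposited tables hold 1 pool of reads per group, with no values per person. The HCC table lists 27767942 autosomal CpGs with a median of 33 reads each, and the control pool had 27799870 CpGs listed with a median of 202 reads. Spread over the members of each group, these depths are 3.30 and 3.96 reads per person. Both tables had at least 10 reads at 27409352 autosomal CpGs, 98.8% of those listed in both, and these were compared. The series title names putative imprinting control regions, short stretches methylated on only one parental copy. The comparisons therefore go from the genome-wide level to regions of intermediate methylation, to known imprinted genes and to promoters of gene lists. With pooled reads there were no replicates, so every test below compares 2 pools of reads and not the people behind them, and every interval covers counting error only.

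The HCC pool was less methylated than the control pool. The mean level over autosomal CpGs was 77.1% in the HCC pool and 78.7% in the control pool, a difference (HCC minus control) of -1.60 percentage points. Its 95% interval of -1.604 to -1.600 takes all reads at all CpGs as independent and is therefore too narrow. The median difference over CpGs was -1.14 points. The level was lower in the HCC pool on all 22 autosomes. Isolated CpGs, with no other measured CpG within 35 bp, differed most, at 79.9% against 82.0% (-2.06 points). Intergenic CpGs differed by -1.70 points and CpGs in gene bodies by -1.63 points. CpGs in promoters of protein-coding genes differed by -0.590 points, and those in 1 kb tiles with at least 50 CpGs by -0.599 points. Without CpGs at a level of exactly 0 or 1 in either pool, and with dense tiles counted on the CpGs left, these were -0.514 and -1.05 points. Counting error brings more CpGs to exactly 0 or 1 in the shallower HCC pool, so this filter can itself shift the difference.

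The size of the difference followed the order in which the deposited tables list the chromosomes, which is 1, 10 to 19, 2, 20 to 22 and then 3 to 9. This was tested after it had been seen in the same values, so the p-values are descriptive. It was 0.0383 points in the first 40 Mb of chromosome 1, -0.520 points from 40 to 80 Mb and -1.21 points from 200 to 240 Mb. Chromosome 10 differed by -1.28 points, chromosome 13 by -1.56 points and chromosome 18 by -1.80 points. From chromosome 2 to the end of the order the 11 chromosomes lay between -1.91 and -1.66 points, with a mean of -1.85. Over the 22 autosomes the difference correlated with the place in the tables (Pearson r = -0.807, Spearman rho = -0.870). Both 2-sided permutation p-values were 1e-05, the smallest that 100000 permutations can give, and were 2e-05 and 3e-05 after Benjamini-Hochberg adjustment over 6 relations. Without the 2 chromosomes farthest from the middle of the order r was -0.871. The chromosome's number gave r = -0.0279 and rho = 0.318, with adjusted permutation p-values of 0.91 and 0.18. CpG density over chromosomes gave r = 0.232 and rho = 0.475 (adjusted permutation p = 0.41 and 0.04). Control depth fell along the same order (rho = -0.765, adjusted permutation p = 0.0001). For HCC depth rho was -0.178 (adjusted permutation p = 0.43). Chromosomes are not independent replicates of the groups, and the relation describes these 2 tables.

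**Figure D1:**
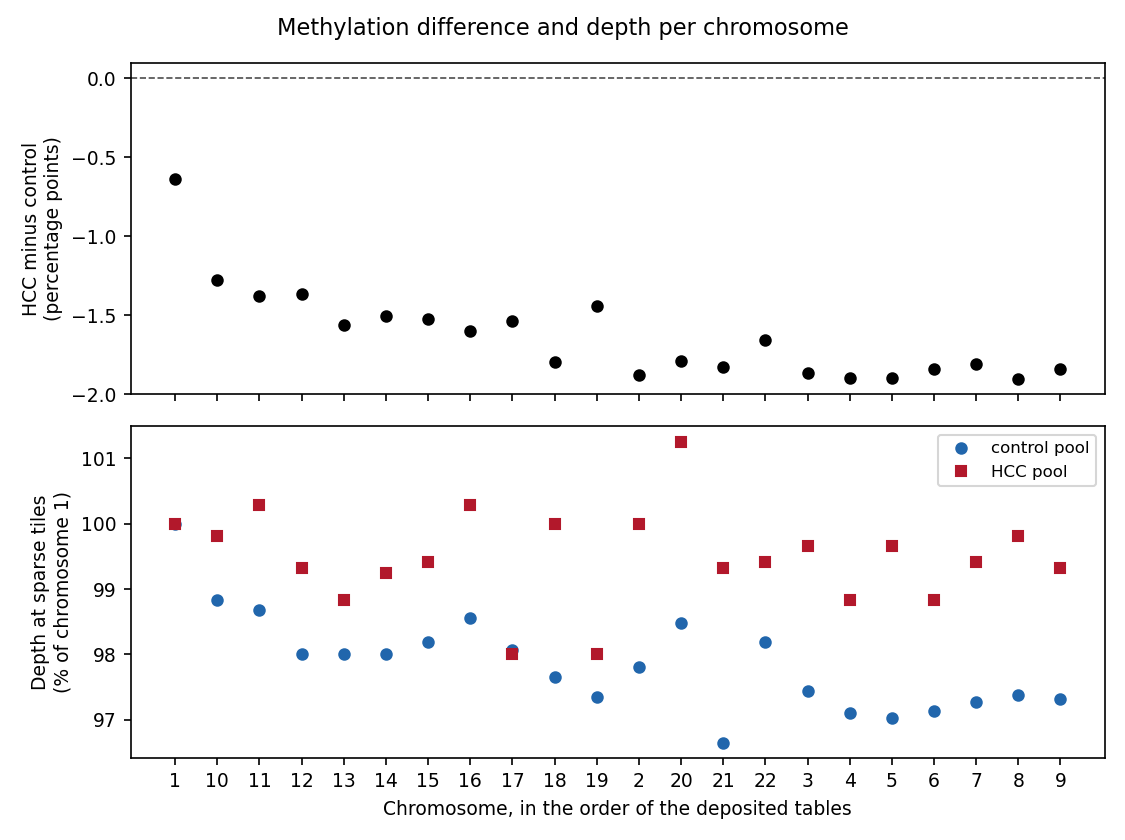
Top, mean methylation difference (HCC minus control, percentage points) of each autosome in the order of the deposited tables; bottom, median depth at 500 bp tiles with 5 to 7 CpGs, as a percentage of that on chromosome 1, for the control pool (circles) and the HCC pool (squares). The difference goes from -0.638 points on chromosome 1 to -1.84 points on chromosome 9, the last in the order.

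Few 1 kb tiles differed by 10 percentage points or more, and most of those that did were lower in the HCC pool. Of 2024892 tiles with at least 5 CpGs, 15392 (0.760%) were lower by at least 10 points and 4079 (0.201%) were higher. Centred on the median tile difference of -1.71 points, the counts were 6683 lower and 7541 higher. With the drop expected from the depth ratio of methylated to unmethylated tiles removed, an alternative chosen after seeing the data, 4424 were lower and 13453 higher. This expected drop was larger than the one seen at dense tiles of intermediate level (-8.88 against -3.21 points), so the alternative can overcorrect. On the 11 chromosomes at the end of the tables' order, 10152 tiles were lower and 542 higher. Fisher's exact test with Benjamini-Hochberg adjustment, taking each read at each CpG as independent, passed 14121 of the lower and 3819 of the higher tiles at 0.05. Taking each tile as a single site at its mean depth, it passed 18 and 3. Drawing HCC reads at the control level plus the median difference gave 1472 lower and 29 higher tiles with independent reads, and 182819 lower and 43460 higher with whole reads shared by all CpGs of a tile. The second draw lies far above the counts seen. CpGs of a tile thus do not share reads to that degree, and that draw overstates counting error. Reads of the plus and minus strands come from different molecules, and their differences correlated over tiles with r = 0.0652 (tiles are not replicates). The 51237 tiles lower by at least 10 points on the plus strand averaged -12.8 points there and -3.01 points on the minus strand, against a mean of -2.01 points over all tiles on the minus strand. The 13831 tiles higher by at least 10 points on the plus strand averaged 13.7 points there and -1.55 points on the minus strand.

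Regions of intermediate methylation were lower by at least 10 points in the HCC pool more often than tiles were, while the share of any size below 0 was 74.5% of regions and 76.3% of tiles. Counting error differs between these sets, with a median of 6 CpGs per region and 9 per tile. Per read it is also larger at intermediate levels than at the tiles' median levels of 86.0% (HCC pool) and 87.8% (control pool). The close CpGs of a region can also share reads more than those of a 1 kb tile. How much of the gap between regions and tiles is counting error was not tested. Regions were runs of at least 5 consecutive CpGs at 35 to 65% in the mean of both pools, near the level of a site methylated on one parental copy, and 12861 were found. Their median level was 47.7% in the HCC pool and 52.6% in the control pool, and the median difference was -4.89 points. By at least 10 points, 3366 regions (26.2%) were lower in the HCC pool and 426 (3.31%) were higher. Fisher's exact test with each read at each CpG as independent passed 3182 and 358 of these, and with each region as a single site 31 and 12. Centred on their own median, 1448 regions were lower and 1210 higher. With the expected depth drop removed, 925 were lower and 1940 higher. That correction left a median of 0.334 points at up to 10 CpGs per 500 bp and 4.34 points at over 30. It thus exceeded the drop seen at dense regions. Regions chosen on the control pool alone, which avoids selecting on the shallower HCC reads, gave 3014 lower and 493 higher among 12706. Strand differences correlated with r = 0.199 over regions, more closely than over tiles. The 3991 regions lower by at least 10 points on the plus strand averaged -7.73 points on the minus strand and the 924 higher ones -1.24, against -5.17 over all regions.

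The largest differences lay in short regions, with coordinates on hg38. Of the 10 lowest regions 9 lay within the span of a gene, and of the 10 highest 4 did. A 15-CpG region within RSRC2 (chromosome 12, 122525966 to 122526118) was at 22.7% in the HCC pool and 82.8% in the control pool. Its difference was -60.1 points (95% interval -73.2 to -39.2), with -54.5 points on the plus strand and -44.4 on the minus strand, at 22.7 and 274.8 reads per CpG. A pair of stretches within B4GALNT4 (chromosome 11, 369970 to 369989 and 369997 to 370018) differed by -57.1 and -48.6 points. Within TENM3 (chromosome 4, 182013987 to 182014102), a teneurin gene, the difference was -50.4 points, and 20660 bp from APOBEC1 (chromosome 12, 7628586 to 7628740) it was -40.1 points over 18 CpGs. Regions within TET3, which encodes a methylcytosine dioxygenase (-52.5 points), FAAH (-41.9), WNK1 (-41.3), SLIT1 (-41.3) and PIH1D1 (-40.7) completed the 10 lowest. At RSRC2, TET3, FAAH, SLIT1 and near APOBEC1, 5 of the 10 lowest, the difference lay beyond those of both strands, as it did in 2 of the 10 highest. On the plus strand TET3 was at -42.5 points and SLIT1 at -28.9. On the minus strand the TET3, SLIT1, WNK1 and FAAH regions differed by -1.72, -0.348, 1.64 and 5.79 points, and WNK1 was at -56.3 points on the plus strand. Among the 10 highest were regions within RAE1 (54.6 points), FAM174B (39.6), PCBD2 (37.2) and the uncharacterised gene LOC124905351 (36.2). The others lay outside genes, 13 bp from LOC105371206 (45.5 points), 49 bp from LOC124907854 (34.2), 6987 bp from LOC100419924 (36.4) and 7994 bp from RPL23AP4 (44.3). For LOC101929814 (37.9) and DISC1FP1 (33.7) the nearest gene was 40040 and 92206 bp away. On the plus and minus strands RAE1 was at 70.4 and 6.74 points and LOC124907854 at -49.5 and 76.9, while PCBD2 was at 16.1 and 18.5. The strands had the same sign in 8 of the 10 lowest regions and 5 of the 10 highest, and 3 of each set had over 3 times the median depth of a pool, which reads from repeated copies of a sequence would give.

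Known imprinted genes had lower levels in the HCC pool at most of the loci measured, each the region with most CpGs near a gene. Of 54 autosomal genes on the imprinted list, 46 had a region of intermediate methylation within 10 kb, at 41 separate loci, and 35 of the 41 loci were lower in the HCC pool. The median locus was at 42.4% in the HCC pool and 48.2% in the control pool, and the median difference was -6.14 points (quartiles -11.5 and -3.75). At 32 loci both strands were lower. With the expected depth drop removed, the median was 1.38 points and 17 of the 41 loci lay below 0. The same correction exceeded the drop seen at other dense tiles of intermediate level (-8.88 against -3.21 points). By at least 10 points 12 loci were lower and 2 higher. Fisher's exact test passed 29 of the 41 loci with reads at each CpG taken as independent (31 adjusted over the list alone). With each locus as a single site it passed 0 of them, at an adjusted p under 0.05, also when adjusted over the list alone, but on simulated tiles this form recovered 0% of changes of 10 points.

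At the 10 best-known imprinted loci, 9 of the differences were below 0, and how many passed depended on the form of the test. The region upstream of H19, a maternally expressed noncoding RNA (chromosome 11, 2002076 to 2002682), was at 42.7% in the HCC pool and 43.2% in the control pool, a difference of -0.539 points (95% interval -18.1 to 18.1, with the locus as a single site). At KCNQ1OT1, an antisense transcript of the same chromosome arm, the difference was -3.75 points, and at SNRPN, in the Prader-Willi region of chromosome 15, -1.52 points. MEST (-4.55 points), PEG3 (-5.55), GNAS (-4.16), MEG3 (-5.35) and PEG10 (-2.86) were lower, and PLAGL1 differed by 1.39 points. At GRB10, a growth factor receptor adaptor (chromosome 7, 50782219 to 50782358), the difference was -11.7 points (-26.8 to 6.44), with -0.603 points on the minus strand. Fisher's exact test with independent reads gave an adjusted p of 7.25e-08 for GRB10, 4.22e-06 for GNAS, 0.000503 for MEST, 0.000661 for MEG3, 0.00108 for PEG3 and 0.0404 for KCNQ1OT1. It gave 0.191 for PEG10, 0.518 for SNRPN, 0.667 for PLAGL1 and 0.861 for H19. These p-values are too small where CpGs share reads. In the simulation with whole reads shared by all CpGs of a tile, this form called 48.7% of unchanged tiles. With each locus as a single site none of the 10 passed, in a form that recovered 0% of simulated changes of 10 points. Chosen on the control pool alone, longer regions at these genes gave -18.0 points for GRB10 over 73 CpGs, -10.98 for PEG10 over 110, -9.55 for MEST over 166, -8.44 for GNAS over 252, -7.92 for MEG3 over 131 and -7.55 for KCNQ1OT1 over 122. The others were PEG3 (-7.00 over 106 CpGs), PLAGL1 (-5.87 over 96, adjusted p = 1.34e-07 with independent reads), SNRPN (-3.88 over 52) and H19 (-2.70 over 64). With the expected depth drop removed, GRB10 was at -1.21 points and the other 9 lay between 2.44 and 11.5 points, MEST at 5.30 and PEG3 at 4.99. Since that correction exceeded the drop seen at other dense tiles of intermediate level, these values above 0 may be overcorrection.

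Other imprinted genes had regions that differed by at least 10 points. INPP5F was at -27.5 points over 15 CpGs (chromosome 10, 119818605 to 119818716; 95% interval -46.5 to -5.18), with -8.01 points on the minus strand, and a different region chosen on the control pool alone gave 1.86 points. SNU13 (-17.0 points), the region shared by BLCAP and NNAT (-16.1), NDN (-14.6), L3MBTL1 (-14.0), FAM50B (-13.3), DIRAS3 (-12.6), IGF1R (-12.5), MKRN3 (-12.3), GET1 (-11.5) and PPIEL (-11.4) were lower. NDN rested on 7 CpGs with opposite strands (14.1 and -40.4 points), and L3MBTL1 was at -2.10 points on the plus strand and -26.1 on the minus strand. Removing the expected depth drop put these regions, from SNU13 to PPIEL, between -6.84 and -1.11 points, and left INPP5F at -17.1. The levels of the BLCAP and NNAT region (chromosome 20, 37521093 to 37521576, 48 CpGs) were 40.3% and 56.4%, at 26.6 and 196.3 reads per CpG. KCNK9 (17.3 points over 9 CpGs, with -15.0 points on the plus strand and 28.2 on the minus strand) and IGF2 (14.2 points over 10 CpGs, chromosome 11, 2146372 to 2146593) were higher, and the IGF2 region chosen on the control pool alone gave -4.35 points. With the expected depth drop removed KCNK9 was at 23.5 points and IGF2 at 21.8.

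**Figure D2:**
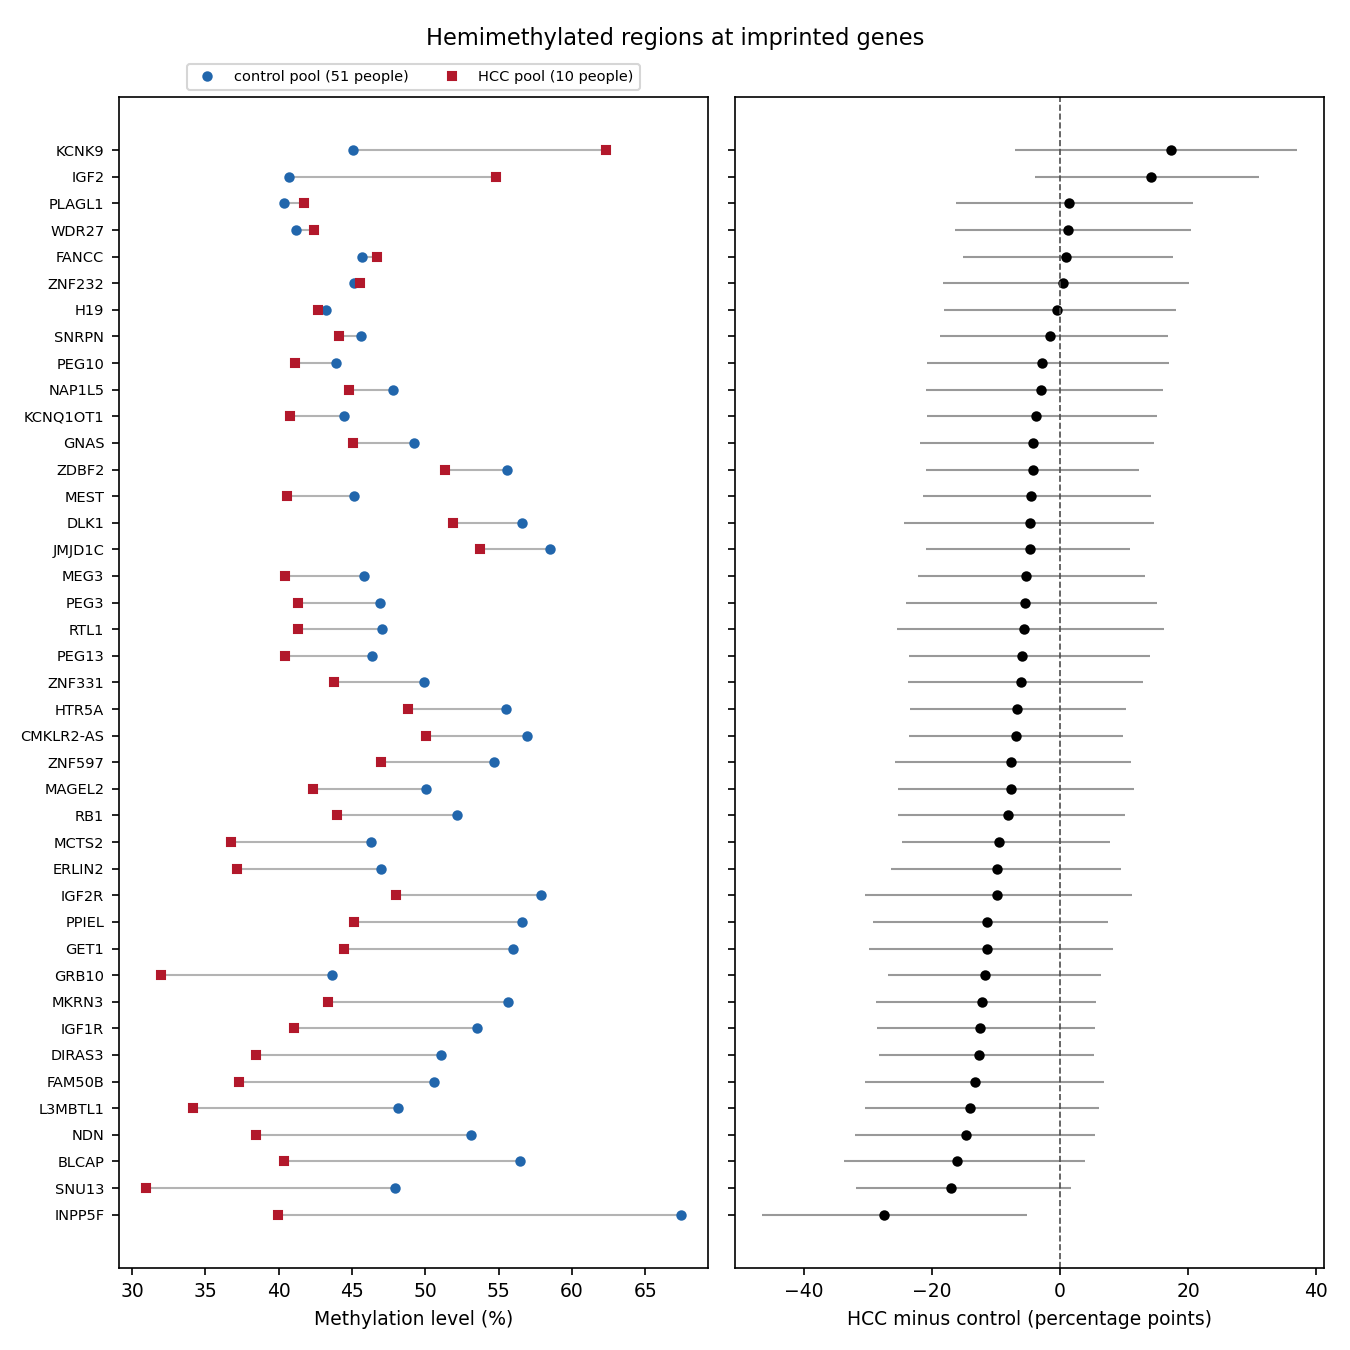
Methylation levels of the 41 loci at imprinted genes in the HCC and control pools (left, percent) and their differences with 95% intervals that take each locus as a single site at its mean depth (right, HCC minus control, percentage points). The gene is the first of those that share a locus. Of the 41 loci 35 lie below 0, and most intervals include 0.

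The lower level at imprinted genes was also found at other regions of intermediate methylation. Among 10000 random lists of 41 other regions matched on the number of CpGs, the median was -9.03 points and the middle 95% ran from -12.2 to -4.81 points, so the imprinted loci lay at the 87.4th percentile. With regions chosen on the control pool alone the imprinted median was -7.82 points, at the 40.3rd percentile of lists matched on the number of CpGs. Matched on CpG density instead, these lists had a median of -5.09 points and the imprinted loci lay at the 4.38th percentile.

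Read depth differed between the pools in step with methylation and CpG density, at the same kinds of region. In 500 bp tiles over 90% methylated in the controls, HCC depth over control depth, relative to its median, was 1.02 at 5 to 7 CpGs and 0.652 at 41 or more. In tiles under 5% methylated it was 1.19 and 1.02. The median control depth of the methylated tiles was 202.6 reads at 5 to 7 CpGs and 183.3 reads at 41 or more, and the HCC depth was 33.5 and 19.1 reads. At tiles of 35 to 65% with 41 or more CpGs the relative depth was 0.775 and the median methylation difference -3.89 points. Methylated CpG-dense sequence was thus read less in the HCC pool, relative to unmethylated sequence, than in the control pool.

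**Figure D3:**
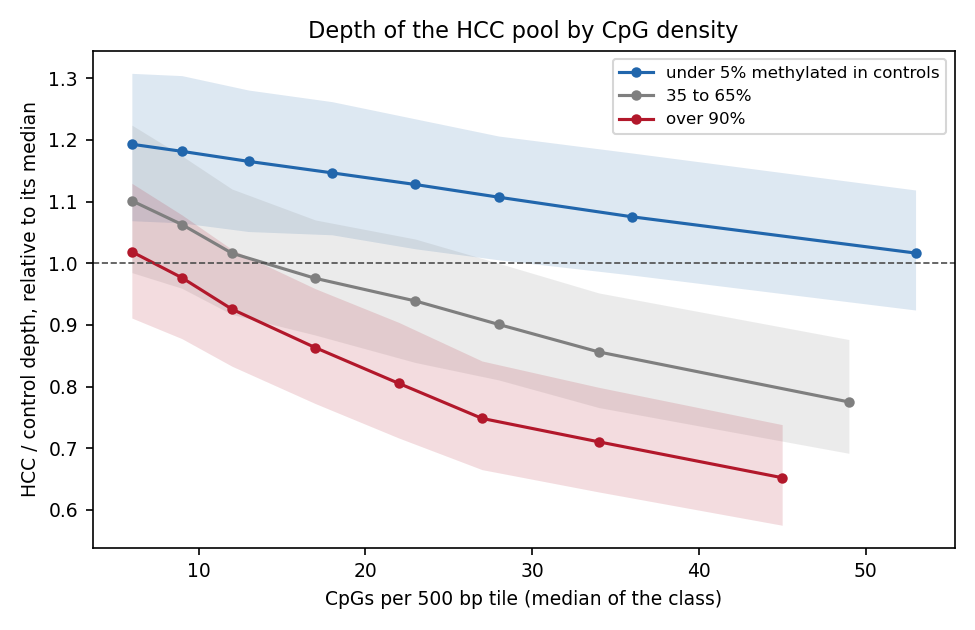
HCC depth divided by control depth, relative to the median over tiles (y axis, no unit), against the number of CpGs per 500 bp tile (x axis), for tiles under 5%, 35 to 65% and over 90% methylated in the control pool. Points are medians and bands run from the lower to the upper quartile of tiles; at the densest class the medians are 1.02, 0.775 and 0.652.

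Promoters differed less than regions of intermediate methylation. The gene table used gives no strand, so the promoter of a gene was taken as the CpG-richer of its 2 ends. For some genes this is the far end, so the value of a single gene below need not be that of its promoter. Among 18908 protein-coding genes with at least 10 CpGs in that window the median difference was -0.660 points, 30 promoters were lower by at least 10 points and 3 were higher. All of these passed Fisher's exact test with independent reads. With single sites 0 promoters passed, and 3 of the 18908 had an unadjusted p under 0.05. On simulated tiles this form recovered 0% of changes of 10 points, so its lack of calls says little about differences of this size. The 10 lowest had the same sign on both strands. PRKAR1A, a regulatory subunit of protein kinase A (chromosome 17, 68412123 to 68414123), was at 33.6% in the HCC pool and 53.2% in the control pool (-19.6 points, 95% interval -33.4 to -2.99), with -21.1 and -18.1 points on the 2 strands. LOC124901163 (-19.9 points), SPINK9 (-18.7), MAP3K7CL (-18.6), the interferon-induced IFITM1 (-17.4), BRF2 (-15.9), SLC9C1 (-14.4), SRPRB (-13.1), the imprinted ZNF597 (-12.9) and the glutamate receptor gene GRM2 (-12.8) were the other 9. A window of 500 bp on each side of the gene end gave -3.07 points at IFITM1, -7.63 at SPINK9 and 0.268 at BRF2, and -24.1 at SLC9C1. The 10 highest included LOC124905351 (18.3 points), GOLGA8A (16.3), INSC (15.9) and CYP4X1 (8.82, and 4.33 with 500 bp on each side), and the strands had the same sign in 4 of the 10. Of these 10 genes 6 lie on chromosome 1, which holds 10.8% of the promoters and comes first in the tables. INSC gave -1.73 points with 500 bp on each side.

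Promoters of 13 of the 14 gene lists had a median below 0, and 4 lists lay outside the middle 95% of 10000 random lists matched on level and number of CpGs, where chance gives 0.7. Imprinted genes had a median of -1.66 points (54 genes, 43 lower and 11 higher), at the 0.02nd percentile. Fisher's exact test with independent reads passed 24 of the lower and 3 of the higher promoters over all genes, and 28 and 3 adjusted over the list alone. ZNF597 (-12.9 points) and PEG13 (-12.6) were lowest, and PXDC1 (1.08) and WDR27 (1.03) highest. On the 11 last chromosomes the list's median was -1.28 points, at the 2.54th percentile. With windows of 500 bp on each side it was -1.13 points at the 1.5th percentile, and over whole gene bodies -2.44 points, below every random list. These lists were matched on a window's mean level, not on whether its single CpGs were of intermediate level. Among regions of intermediate methylation the imprinted loci lay at the 87.4th percentile. Chosen on the control pool they lay at the 40.3rd, or at the 4.38th when matched on CpG density. The drop expected from depth was not removed for the promoter lists. With each promoter as a single site, none of any list passed, over all genes or adjusted over the list alone. This form recovered 0% of simulated changes of 10 points in tiles, so it could hardly have called differences this small.

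Hepatocyte markers, genes whose products are made mainly by liver cells, had a median of -2.33 points at the 0.97th percentile, with 24 of 26 lower. The test with independent reads passed 9 of the lower and 0 of the higher promoters (10 and 0 adjusted over the list alone). APOB, the main apolipoprotein of low-density lipoprotein (chromosome 2), was at 29.1% against 39.9% (-10.8 points, 95% interval -25.7 to 8.39), and CRP, an acute-phase protein, differed by -6.22 points. APOA2 (0.868 points) and CPS1 (0.792), a urea cycle enzyme, were highest. With windows of 500 bp on each side the median of this list was -2.34 points at the 6.92th percentile, and on the 11 last chromosomes -2.28 points at the 15.2nd, both inside the random range. With at least 10 CpGs per promoter the list lay at the 0.84th percentile. Over whole gene bodies its median of -2.48 points lay below every random list.

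Markers of blood cell types lay within the range of random lists in the promoter window used. With 500 bp on each side NK cell markers (-4.18 points, 1.78th percentile) and B cell markers (0.0933 points, 98.9th percentile) lay outside it, and over whole gene bodies T cell markers did (-2.44 points, below every random list). Neutrophil markers had a median of -2.30 points at the 11.6th percentile, with 7 of 20 lower and 1 higher by the test with independent reads (9 and 1 adjusted over the list alone). CXCR2, a chemokine receptor, differed by -6.82 points and MPO, myeloperoxidase, by -6.43, while S100A12 (4.79) and CEACAM8 (1.70) were highest. Values of single markers are those of the CpG-richer gene end, which need not be the promoter. Monocyte markers had a median of -2.53 points at the 9.58th percentile, with CD14 (-7.37) and CD300E (-5.28) lowest and MS4A6A (1.21) highest. The test passed 1 of the 10 as lower, also adjusted over the list alone. T cell markers had a median of -2.02 points at the 12.02nd percentile, with 6 of 20 lower by the test (7 adjusted over the list alone). CD247, a T cell receptor chain (-8.85 points), and CD3G (-4.85) were lowest and CD4 (0.980) highest. NK cell markers had a median of -2.59 points at the 12.6th percentile, with 5 lower and 1 higher of 14 by the test (6 and 1 adjusted over the list alone). KLRD1 (-5.16) and CD160 (-5.03) were lowest and KLRF1 (5.10) and XCL2 (2.83) highest. B cell markers had a median of -0.402 points at the 95.7th percentile, with 3 lower and 1 higher of 16 by the test, the same counts adjusted over the list alone. TCL1A (-6.85) and POU2AF1 (-4.96) were lowest, and MS4A1, a B cell surface protein (10.96, from 7 CpGs), and FCRL1 (1.58) highest. Eosinophil and basophil markers had a median of -0.909 points at the 88.7th percentile, with 3 of 11 lower by the test, also adjusted over the list alone. IL5RA (-4.93) and PRG3 (-4.67) were lowest and SIGLEC8 (1.251) and MS4A2 (0.463) highest. Erythroid markers had a median of -2.49 points at the 14.3rd percentile, with 3 of 11 lower by the test (4 adjusted over the list alone). GYPB (-4.69) and HBB (-4.63) were lowest and HBA1 (0.269) and HBG2 (0.167) highest.

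Promoters often methylated in liver tumours were not higher in the HCC pool. The list of tumour-methylated promoters had a median of -0.606 points at the 22.6th percentile, with 23 of 30 genes lower. The test with independent reads passed 9 lower and 1 higher, over all genes and adjusted over the list alone. RUNX3 (-7.50 points) and TSPYL5 (-2.67) were lowest. CCND2, cyclin D2, was at 3.39% in the HCC pool and 1.18% in the control pool (2.20 points, 95% interval -1.62 to 15.5), and ZNF154 differed by 1.91 points. The age-, smoking- and inflammation-associated lists were scored over the window at the CpG-richer gene end. Single associated CpGs were not looked up, so the values need not be those of such sites. Age-associated sites had a median of -1.01 points at the 26.5th percentile, with 1 of 15 lower by the test, also adjusted over the list alone. MIR29B2CHG (-2.98) and FHL2 (-2.68) were lowest and SST (1.45) and ELOVL2 (0.192) highest. Inflammation-associated sites had a median of -0.621 points at the 70.6th percentile. IFITM1 was the 1 promoter of 14 that was lower by the size rule, the test passed 1 as lower, also adjusted over the list alone, and ABCG1 differed by -1.96 points. CPT1A (1.19) and NLRC5 (0.279) were highest. Smoking-associated sites had a median of -1.76 points at the 2.26th percentile over 8 genes, with 3 lower by the test (4 adjusted over the list alone). MYO1G (-7.20) and GPR15 (-4.00) were lowest and GFI1 (0.573) and AHRR (0.281) highest. With at least 10 CpGs per promoter its percentile was 3.58, with windows of 500 bp on each side 24.4 and over whole gene bodies 5.73. The DNA methylation machinery was the 1 list with a median above 0, at 0.168 points and the 99.7th percentile, with 3 higher and 2 lower of 14 by the test, the same counts adjusted over the list alone. NLRP7 (3.32) and ZNF445 (1.80) were highest, and ZFP57, which maintains methylation at imprinted loci (-6.59), and DNMT3L (-4.73) lowest. Its median was -0.592 points (36.8th percentile) with windows of 500 bp on each side, -1.46 points (71.7th) over whole gene bodies and -1.38 points on the 11 last chromosomes.

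**Figure D4:**
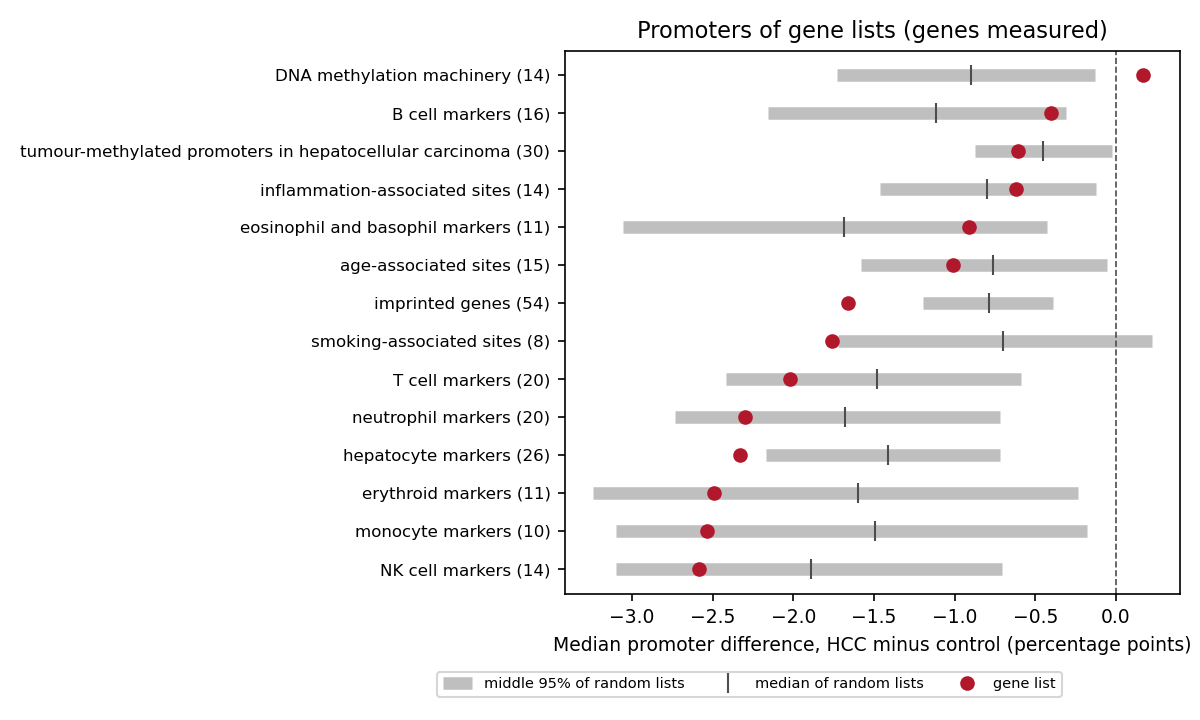
Median promoter difference (HCC minus control, percentage points) of the 14 gene lists (circles), with the median (ticks) and middle 95% (bars) of 10000 random lists matched on level and number of CpGs; genes measured are in parentheses. Imprinted genes (-1.66), smoking-associated sites (-1.76) and hepatocyte markers (-2.33) lie below their bars and the DNA methylation machinery (0.168) above.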

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

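Alternatives that left out very deep CpGs, removed the drop expected from depth, required each strand by itself, summed methylated reads in the test or kept only the last 11 autosomes in the order of the tables were chosen after seeing the data. Of the planned comparisons with another setting, 45 values answering a comparison stayed near the count reported, within its error or on the same side of the random range, as did 18 of the added ones. Of the other planned values 26 moved, 3 reversed, 4 became weaker and 2 stronger. Of the other added values 18 moved, 3 reversed and 3 became weaker. Single genes or regions stayed within the 95% counting interval of the value reported in 236 planned and 62 added comparisons, but these intervals are wide: 36 and 8 of them changed sign, 14 and 12 came under 10 points, and 5 and 1 came over. In the planned comparisons of single genes or regions 3 other values moved and 7 reversed. For all other values given here the cause was not tested, unless the alternative by construction has fewer regions. The genome-wide difference was -1.60 points with both strands measured, -1.59 with a minimum of 5 reads, -1.64 with 20 reads, -2.24 without CpGs at 0 or 1, -1.14 as a median, -1.61 without very deep CpGs and -1.85 on the last autosomes. Without CpGs at 0 or 1, promoters differed by -0.514 points, gene bodies by -2.35, intergenic CpGs by -2.22, CpG-dense tiles by -1.05 and isolated CpGs by -2.39. Counting error brings more CpGs to exactly 1 in the shallower HCC pool, so this filter can itself lower the difference at methylated CpGs. Isolated CpGs were then defined among the CpGs left, 10076116 against 9969679 before. On the last autosomes promoters differed by -0.614, gene bodies by -1.89, intergenic CpGs by -1.95 and isolated CpGs by -2.22. Tiles higher and lower numbered 6221 and 24100 at 500 bp, 1025 and 3158 with at least 10 CpGs, 908 and 1670 at a threshold of 15 points, and 7541 and 6683 centred on the median. They numbered 13453 and 4424 with the expected depth drop removed, 212 and 3955 on each strand by itself, and 542 and 10152 on the last autosomes. Regions of intermediate methylation higher and lower numbered 154 and 1183 in a range of 40 to 60%, 35 and 553 with at least 10 CpGs, 148 and 1416 at 15 points, and 1210 and 1448 centred. They numbered 1940 and 925 with the expected depth drop removed, 141 and 1580 on each strand, and 219 and 1599 on the last autosomes. The imprinted loci reversed to a median of 1.38 points with the expected depth drop removed, where the same correction expected -8.88 points at other dense tiles of intermediate level and -3.21 were seen. With promoter windows of 500 bp on each side, the median of B cell markers reversed to 0.0933 points and that of the DNA methylation machinery to -0.592. In the same windows B cell and NK cell markers (-4.18) came to lie outside the random range, and hepatocyte markers (-2.34) and smoking-associated sites (-0.880) inside it. Over whole gene bodies T cell markers (-2.44) came to lie outside it, smoking-associated sites (-2.10) inside it, and the DNA methylation machinery reversed to -1.46. Smoking-associated sites also lay inside it with at least 10 CpGs (-1.76). On the last autosomes imprinted genes (-1.28), hepatocyte markers (-2.28) and smoking-associated sites (-2.42) lay inside it, and B cell markers (0.396) and the DNA methylation machinery (-1.38) reversed. Single genes that differed by at least 10 points reversed with regions chosen on the control pool (INPP5F, 1.86, and IGF2, -4.35), with windows of 500 bp (BRF2, 0.268, and INSC, -1.73) and over whole gene bodies (IFITM1, 0.414, INSC, -1.92, and MS4A1, -2.52). Of 45 imprinted genes with a region under both selections, 6 changed sign, PLAGL1 (-5.87) among them. The permutation test over people was not run, because the tables hold pools, and isolated CpGs were not split by flanking bases. At 33 reads per CpG in the HCC pool, the test that takes a locus as a single site recovered 0% of simulated changes of 10 points in tiles, so that its lack of calls at imprinted loci says little about differences of that size.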

Other observations

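All tests in this part were set after the results they bear on had been seen, and for the imprinted loci and the genome-wide level more than one criterion was tried. Mitochondrial CpGs, which are read here only as a measure of conversion, were at 1.15% in the HCC pool and 1.61% in the control pool over 435 CpGs. Their median depth was 83.3 times the autosomal median in the HCC pool and 147 times in the control pool. Regions of intermediate methylation chosen on the control pool differed by a median of -3.54 points at up to 10 CpGs per 500 bp and -5.68 points at over 30.

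The methylation difference and the control depth both followed the order of chromosomes in the deposited tables. A different CpG density of the chromosomes was argued against as the cause. At tiles of 5 to 7 CpGs the range over chromosomes was still 1.02 points, of 1.27 points over all CpGs. Other sequence features of the chromosomes were not tested. A candidate explanation is that some control libraries stop part of the way through that order: control depth changed by -4.27% from the first 40 Mb of chromosome 1 to the last autosomes, and HCC depth by -1.16%. For the control level of the most methylated tiles to shift by 1.01 points, as it did, the lost reads would have to lie 23.6 points below the rest, and no value per library shows whether any did. This stays open, as does any other change of the control pool along the tables, and no biological explanation of this order was tested.

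The genome-wide level was lower in the HCC pool. Loss of CpG-dense methylated fragments from the HCC libraries was argued against as the whole cause, since tiles over 90% methylated differed by -0.971 points in the densest class and -1.76 points in the sparsest, where the depth ratio expected -2.08 and -1.03, although its expected mean of -2.06 points is large enough for the -1.65 points seen over all 500 bp tiles, so that a part stays open. Unconverted cytosines in the control libraries were argued against because the mitochondrial difference of -0.460 points was smaller than the -1.55 points at methylated tiles. Incomplete protection of methylated cytosines in the HCC libraries, as an equal share at every density, was argued against by a loss of 1.01% in the densest class and 1.86% in the sparsest. A change of the control pool along the tables, a single poor library in a pool and a difference between people with and without the cancer, in blood cell types or otherwise, stay open and were not tested as causes. Marker lists of blood cell types were compared with random lists, where the outcome changed with the window. Cell shares were not estimated.

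Imprinted loci were lower in the HCC pool, by a median of -7.82 points where regions were chosen on the control pool. Loss of CpG-dense methylated fragments may account for this, with an expected median drop of -9.55 points, but the same ratio predicts -8.88 points at other dense tiles of intermediate level, where -3.21 points were seen; it met a first criterion without that comparison. Tumour DNA of liver origin would need a share of 15.8%, which would put hepatocyte marker promoters at -11.5 points relative to all promoters, and their mean was -1.36 points (SE 0.465). That value had counted against liver DNA under a first criterion. It argues against such DNA as the whole cause if that DNA is unmethylated at these promoters, as was assumed. Whether such DNA is unmethylated there was not measured, and a smaller share stays open. Lower methylation specific to imprinted loci is also open, at the 4.38th percentile of lists matched on CpG density, and at the 16.5th (1.80 points against 3.39 in random lists) with the drop expected from depth removed.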
